A study of Homo sapiens with 5 samples.

How the data were processed

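RNA was sequenced from 5 libraries of HEK 293T cells, 2 controls, 2 after 3 days of 1 µM 5-aza-2'-deoxycytidine and 1 after 30 days of recovery; groups were taken from the sample titles and source names. Per the labels, total RNA was extracted with Trizol, depleted of ribosomal RNA with Ribo-Zero, and made into directional libraries by dU marking. Cells were grown in triplicate, per the labels, but nothing says which cultures the libraries came from, so a difference between libraries of 1 group may be technical. Expression was estimated with Cufflinks and Cuffdiff, per the submitters' processing notes, which name no versions and list the builds hg19 and mm9; the coordinates of these human tables are taken as hg19. The aligner, the gene annotation release and the Cuffdiff settings are not given in the sources used here.

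The authors deposited FPKM values, 1 per gene and group with the replicates already combined, per the file headers. Per the file headers the authors also deposited a q-value (a p-value adjusted for multiple testing) for treated and for recovery against control, a yes or no call for each, and 2 marks headed SOM, an abbreviation that the sources used here do not spell out. The calls were yes exactly where q was under 0.05. The number of value columns that could not be matched to a group was 0. In 1 of 20221 RefSeq entries and 2 of 21627 lncRNA entries an exponent had lost its minus sign and later cells were shifted, so these were left out, leaving 20220 and 21625; 2 unnamed columns of the lncRNA table hold only text pushed out of such entries. The lncRNA transcripts of 1 locus repeat the same values and were counted as 1 locus, 10010 in all. Control, treated and recovery values were listed at 0 in 7562, 5376 and 6547 RefSeq entries. The 10 highest RefSeq entries held 67.2%, 67.2% and 69.5% of the summed FPKM.

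RefSeq identifiers were matched to symbols with NCBI's RefSeq gene table (GRCh38.p14, used for names and neighbours only), and 19665 of 20220 matched. The RefSeq table has 1 entry per locus, so overlapping genes can share an entry, and 16485 of 20056 protein-coding symbols have an entry of their own. Coordinates are printed 1-based.

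Depth was read from the low values. In the RefSeq table the commonest ratio of 2 group values was taken as that of 1 fragment against 1 fragment. It was 0.757 for treated over control (92 of 12366 genes above 0 in both) and 1.53 for recovery over control (101 of 12095). Of 11983 genes above 0 in all groups, 299 gave whole numbers with 1 control fragment, against 19.2 by chance, and 688 did with 1 to 5; the search gave no whole numbers for the rest. The smallest whole numbers of fragments that give a gene's 3 values were searched with up to 5 fragments in control and a tolerance of 0.02 fragments; a match at a given control number has a chance of 0.16%. They are smallest numbers, and a multiple of them would give the same values.

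The planned model on single libraries could not be run because only group values were deposited. As written before the data were examined for that case, the counts of changed genes are the authors' calls at q under 0.05, with the direction from the group values, and no test per gene was added. Size is given as the FPKM of each group and their ratio, and no ratio is given against a group listed at 0. Log2 changes are differences of log2(FPKM + 1), a pseudocount of 1 that understates the change of low genes. The correlation and the list medians used genes with a mean of 0.5 FPKM or more over the 3 groups.

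The 25 gene lists were fixed before the data were examined. Enrichment of calls in a list was tested with a one-sided Fisher's exact test per direction among genes with q under 1, for lists with at least 5 such members, with Benjamini-Hochberg adjustment over lists and directions (44 tests for treated, 46 for recovery); this test replaced the planned set test after the data were seen. A count adjusted over the list alone could not be made because the tables give q and not p. Members are counted as measured. Those without a q under 1 may not have been tested, so members that did not pass include them. A list's median is also set among 10000 random lists matched on mean expression in 20 bins, as a description. The mean was that of the 3 groups, so lists were not matched on control level. On simulated lists of 40 among 12712 genes for treated against control, 8% of 100 unchanged lists, 92% at a 1.5-fold change and 100% at a 2-fold change lay outside the central 95%. The simulated changes had no floor at 0. Chromosome and mark enrichments used two-sided Fisher's exact tests; after the data were seen, these and the germline list were also tested apart for genes at 0 and above 0 in control. The retained share is the recovery log2 change divided by the treated one, with an interval from 10000 bootstrap draws over genes; its value for unchanged groups against a shared control was simulated after the data were seen.

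The named genes are those with the largest log2 change among the called RefSeq genes, 10 higher and 10 lower for treated and 5 and 5 for recovery, leaving out symbols that start with SNORD, SNORA, SCARNA, RNU, RN5S, RNY, MIRLET, or MIR or LOC and a digit, together with DNMT1, DNMT3A, DNMT3B and UHRF1 and up to 4 members per list. The rule also asked for values of both replicates on 1 side, which could not be applied, and ranked list members by a test statistic, for which the call and then the size of the log2 change were used. Genes named beyond the rule are said to be so, and 1 gene that the rule names is not reported here. Of unnamed lncRNA loci, 2 that rose and 2 that fell are printed. The alternatives tried were another pseudocount, other filters, median-ratio and quantile scaling, an added fold threshold and those chosen later, listed with their effect in the closing part. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.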

Results

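Gene expression was measured by RNA sequencing in HEK 293T, a human embryonic kidney cell line that carries the SV40 large T antigen. The cells were exposed for 3 days to 1 µM 5-aza-2'-deoxycytidine, a cytidine analogue that is built into DNA and traps DNA methyltransferases, so that methylation is lost as cells divide. There were 2 control libraries without drug, 2 libraries from treated cells and 1 library from cells kept for a further 30 days without the drug. The libraries were made from RNA depleted of ribosomal RNA. The authors deposited 1 FPKM value (fragments scaled to transcript length and sequencing depth) for each group, not for each library, in a table of 20221 RefSeq gene entries and a table of 21627 long noncoding RNA (lncRNA) transcripts. The spread between replicates is therefore not shown by these values, no SD or n of its own stands beside them, and the only tests per gene are the authors' q-values against control. Total fragments per library are not given either, but some low FPKM stand in whole-number ratios between groups, from which the value of 1 fragment was estimated. That value was 0.757 times the control's in treated cells and 1.53 times the control's in recovery, so the treated values rested on 1.32 times and the recovery values on 0.652 times as many fragments as the control values.

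The first question was which genes changed while the drug was present. In the authors' deposited table, 122 RefSeq genes were higher and 31 were lower in treated than in control cells at q under 0.05. Germline genes were among those that rose. TKTL1, a transketolase-like gene listed among cancer-testis genes (X chromosome, 153524027 to 153558713, hg19), went from 2.42 to 100 FPKM (41.4-fold), and 3 other germline genes were listed at 0 in control cells: SPANXC, a sperm protein gene (28.3 FPKM when treated), DAZL, an RNA-binding protein of germ cells (16.6 FPKM), and VCX2 (12.1 FPKM). Of the 73 measured members of the cancer-testis and germline list, 42 of them with q under 1, 13 rose, 0 fell and 60 did not pass. That is more than the list's share of all tested genes (one-sided Fisher's exact test on the authors' calls, adjusted p = 1.28e-14 over 44 tests). Over the 49 members with a mean of 0.5 FPKM or more, the list's median log2 change was 2.83, at percentile 100 of 10000 random lists matched on expression. Of all 73 members, 45 were listed at 0 in control. Such members enter the median only through their treated or recovery values, and the random lists were not matched on control level. Part of the median's height is therefore built in, and the percentile cannot tell how much. Among genes tested from a control at 0, the list held 12 of 106 higher calls and 18 of 296 genes (odds ratio 3.91, two-sided Fisher's exact test, adjusted p = 0.0208 over 16 tests). With a control above 0, it held 1 of 16 higher calls and 24 of 10960 genes (adjusted p = 0.069, same Fisher's exact test). The list holds several members of gene families such as SPANX, VCX, MAGEA, GAGE, PAGE and SSX. How fragments were shared among related members is not given. Values of single members are therefore uncertain, and members may not count as independent genes in these tests.

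Other large rises came from genes of varied function. SNAR-I, a small noncoding RNA, was listed at 0 in control and at 1142 FPKM in treated cells. In entries this short, few fragments give a high FPKM. For SNAR-G2 and SNAR-G1, related entries above 0 in control, a smallest number of 1 control fragment gave 34.7 and 54.3 FPKM. MT1E, a metal-binding metallothionein (chromosome 16, 56659585 to 56661024), reached 34.9 FPKM, DPM3, a subunit of dolichol-phosphate mannose synthase, 36.5 FPKM, S100A6, a calcium-binding protein, 16.6 FPKM, and MAP1LC3A, an autophagy protein, 16.8 FPKM, each from a control listed at 0. SPANXN3 (24.2 FPKM) and the entry of TMEM132D-AS1 (20.3 FPKM), whose span also covers TMEM132D, were likewise listed at 0 in control. Among genes measured above 0 on both sides, TMSB4X, the actin-binding thymosin beta 4, rose from 112 to 609 FPKM (5.42-fold), GPRC5A from 30.0 to 143 FPKM (4.77-fold), and PEG10, an imprinted gene derived from a retrotransposon, from 1.97 to 28.0 FPKM (14.2-fold). Caveolar CAVIN1 rose 3.68-fold, the heparan sulfate proteoglycan gene SDC4 3.83-fold and the receptor gene NOTCH1 3.97-fold; these 3 genes, TMSB4X and GPRC5A lie outside the naming rule and were chosen after their values were seen.

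Among genes that fell were 4 of the stress list. DDIT4, an inhibitor of the growth regulator mTORC1 (chromosome 10, 74033677 to 74035797), went from 154 to 19.7 FPKM (7.84-fold lower), asparagine synthetase ASNS from 137 to 26.4 FPKM (5.21-fold lower), the pseudokinase TRIB3 from 68.8 to 13.4 FPKM (5.14-fold lower), and PHGDH, the entry enzyme of serine synthesis, from 145 to 46.8 FPKM (3.09-fold lower). These were the 4 members of the endoplasmic reticulum and integrated stress list called lower among 23 measured; 0 were called higher and 19 did not pass (one-sided Fisher's exact test, adjusted p = 8.84e-06; median log2 change -0.44, percentile 0.19). ASNS and PHGDH make amino acids, and DDIT4 and TRIB3 act on growth signalling; none of the 4 is a protein-folding chaperone. The other large falls were ABCC6P2, a pseudogene (27.5 FPKM in control), ING2-DT (20.4 FPKM), C6orf52 (14.2 FPKM), HERC2P10 (11.9 FPKM), LINC01556 (10.0 FPKM), ECSCR (9.01 FPKM), LCMT1P1 (8.41 FPKM), NR_033908 (6.17 FPKM) and KRT222 (4.83 FPKM), all listed at 0 in treated cells. ABCC6P2, HERC2P10 and LCMT1P1 are near copies of other genes, so their fragments cannot be assigned with certainty.

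In the heat shock list, 2 of 13 measured genes rose, the chaperone DNAJA1 (56.2 to 180 FPKM, 3.21-fold) and HSPA1B, an inducible HSP70 gene (27.1 to 86.5 FPKM, 3.19-fold), while 0 fell. HSPA8, a constitutive HSP70 family member, was at 230 FPKM in control and 936 FPKM in treated cells, with q = 0.0814 in the authors' deposited table, and HSPA1A, nearly identical to HSPA1B, was at 1.33 and 25.3 FPKM (q = 0.53). The list's calls missed the threshold (one-sided Fisher's exact test, adjusted p = 0.074), and its median log2 change of 0.88 lay at percentile 100. Among 50 measured replication-dependent histone genes 2 fell, H3C4 (2626 to 739 FPKM) and H2AC6 (1301 to 401 FPKM), and 0 rose (adjusted p = 0.074 in the same one-sided Fisher's exact test). The histone list's median log2 change was -0.40 (-0.21 after quantile scaling) and its mean 0.60, of opposite sign. Without a call, 11 members lay at least 10-fold above control; H2BC3 was at 0.805 and 136 FPKM and H1-1 at 0.957 and 119 FPKM.

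Of 34 measured imprinted genes, 3 rose and 0 fell (one-sided Fisher's exact test, adjusted p = 0.0441; median log2 change 0.52, percentile 99.8); the list did not pass with calls at q under 0.10. They were PHLDA2 (0 to 14.2 FPKM), PEG10 and the noncoding MEG3 (0 to 3.64 FPKM). H19, the imprinted noncoding RNA next to IGF2 (chromosome 11, 2016406 to 2019065), was at 9.49 FPKM in control and 490 FPKM in treated cells, a ratio of 51.6, but the authors' deposited table gave q = 0.542. In the HOX list 2 of 28 rose, among them HOXC12 (0 to 8.21 FPKM), with an adjusted p of 0.173 in the one-sided Fisher's exact test and a median at percentile 99.8. Among 13 metallothionein genes 1 rose, MT1E; MT1G was at 0.948 and 15.8 FPKM without a call (one-sided Fisher's exact test, adjusted p = 0.404). In the neuronal list 2 of 28 rose, the neurofilament genes NEFH (0 to 4.82 FPKM) and NEFM (0 to 4.79 FPKM), with adjusted p = 0.0818 in the one-sided Fisher's exact test. The list's median and mean log2 change were -0.22 and 0.40. NR5A1, a steroidogenic transcription factor (0 to 5.28 FPKM), was the 1 call among 22 kidney and adrenal genes. The 1 call among 25 housekeeping genes was POLR2A, the largest subunit of RNA polymerase II (14.7 to 47.7 FPKM), and MEG3 was the 1 call among 32 well-studied long noncoding RNAs.

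The machinery that the drug targets was not called. DNMT1 was at 43.5 FPKM in control and 53.5 FPKM in treated cells, DNMT3A at 5.16 and 9.18 FPKM, DNMT3B at 16.0 and 25.8 FPKM and UHRF1, which guides DNMT1 to replicated DNA, at 35.0 and 29.9 FPKM; the lowest of their q-values in the authors' deposited table was 0.915. In the list of methylation writers, erasers and readers, 0 of 22 genes were called. The interferon and RNA sensing list had 0 calls among 54 measured members, 33 of them with q under 1. ISG15, a ubiquitin-like interferon-induced protein, was at 0.398 and 25.9 FPKM and IFI27 at 0.607 and 15.6 FPKM, while USP18 was at 7.17 and 1.37 FPKM. The p53 and DNA damage list (30 measured), the proliferation list (40), apoptosis genes (27), nucleoside uptake and deoxycytidine metabolism (23), clustered protocadherins (18), methylation-silenced tumour suppressors (36) and cholesterol synthesis (21) each had 0 calls. Of the 18 protocadherins only 5 had q under 1. DCK, the kinase that activates the drug, was at 37.2 and 15.3 FPKM (q = 0.423 in the authors' deposited table) and DKK1, a WNT inhibitor, at 0.231 and 14.3 FPKM (q = 0.939 in the authors' deposited table). Markers of fibroblasts (15 measured), blood cells (20), epithelia (19) and endothelium (14) had 0 calls, and those of blood, epithelia and endothelium had under 5 tested members and no list test. Only 5 blood and 6 epithelial markers had a mean of 0.5 FPKM or more. Their median log2 change was 1.83 for blood (percentile 99.1) and 1.05 for epithelia (percentile 99.1). Both lay above the central 95% of random lists, as for the germline list. In control, 16 of 20 blood and 14 of 19 epithelial markers were listed at 0, and such genes enter the median only through their treated or recovery values. KRT17 was at 17.0 and 73.8 FPKM and KRT19 at 29.9 and 98.7 FPKM. Ribosomal protein genes had 0 of 70 calls and a median log2 change of -0.27, at percentile 0.18; after quantile scaling the median was -0.11.

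Among the higher genes, 106 of 122 were listed at 0 in control cells, and among the lower genes 22 of 31 were listed at 0 in treated cells; restricted to genes above 0 on both sides, 16 were higher and 9 lower. A control value of 0 can be a failed estimate, since DDX3X, which most cells express, was listed at 0 in control. It was at 170 and 126 FPKM in the treated and recovery groups and was chosen after its values were seen. DDX3X had no q under 1 in either comparison, unlike the called genes, so alone it does not show that their control values failed. For called genes outside the germline list, failed estimates stay open. At 0 in control alone, with 1 FPKM or more in both other groups, stood 275 RefSeq genes, against 27 for treated and 56 for recovery. Called genes with this pattern include DPM3 and CDC26. CDC26, chosen after its values were seen, was at 0, 9.63 and 10.2 FPKM in control, treated and recovery.

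**Figure D1:**
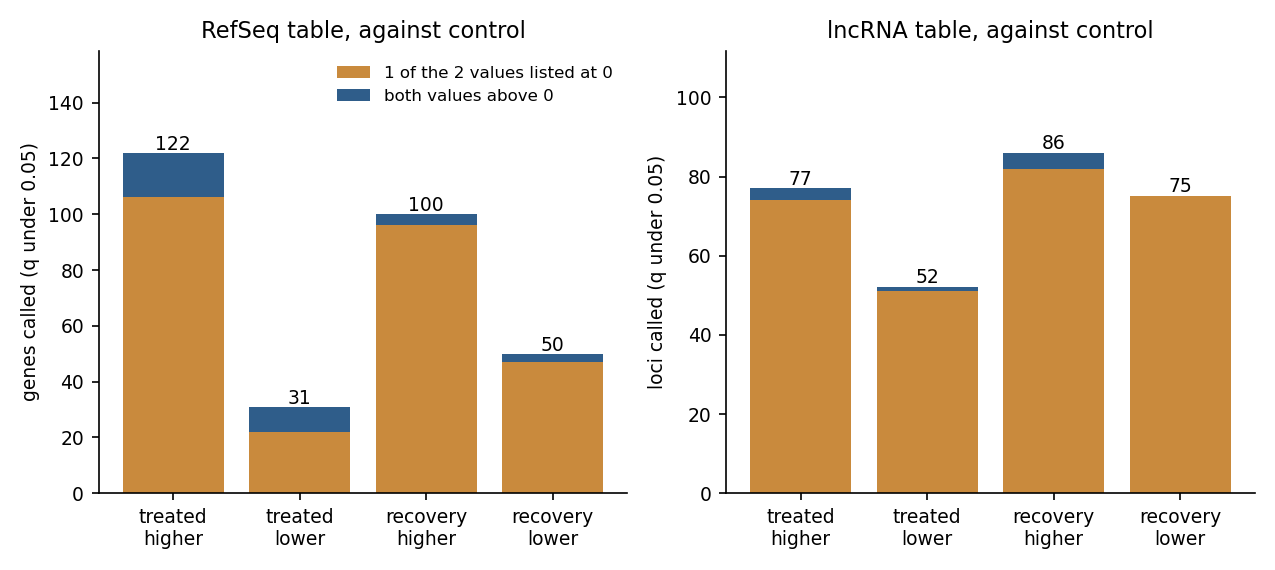
Number of RefSeq genes (left) and lncRNA loci (right) called by the authors at q under 0.05 against control. Bars split each count by whether 1 of the compared group values was listed at 0 (ochre) or both were above 0 (blue); of the 122 RefSeq genes higher in treated cells, 106 had a control listed at 0.

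Genes on the X chromosome were frequent among those that rose with treatment. X-linked genes made up 22 of the 122 higher genes (18.0%) against 3.82% of the genes tested (odds ratio 5.78, two-sided Fisher's exact test, adjusted p = 8.28e-09 over 8 tests). Without the cancer-testis and germline list, 14 of 109 higher genes were X-linked (adjusted p = 8.12e-05, Fisher's exact test). Split by control, X-linked genes were 17 of 106 higher calls from a control at 0 against 11.1% of such genes tested (two-sided Fisher's exact test, adjusted p = 0.0962 over 16 tests). From a control above 0 they were 5 of 16 against 3.62% (adjusted p = 0.00305 in the same Fisher's exact test). Without the list they were 10 of 94 against 7.91% from a control at 0 (adjusted p = 0.328, same Fisher's exact test). From a control above 0 they were then 4 of 15 against 3.50% (adjusted p = 0.0119, same Fisher's exact test). The X-linked genes outside the list included the zinc finger gene ZNF711 (30.3 to 129 FPKM), TMSB4X, ZCCHC12 (6.58 to 60.6 FPKM), HMGB3 (25.9 to 80.3 FPKM) and BEX1 (0 to 11.7 FPKM); USP26, RHOXF1, SPANXN3 and CT55, outside the list, are also known from testis. ZNF711, ZCCHC12, HMGB3, USP26, RHOXF1 and CT55 were named after their values were seen. Of the 31 lower genes 1 was X-linked. The authors' deposited table also marks genes as affected in DNA methylation, without saying how the marks were made. The mark was on 30 of the 122 higher genes (24.6%) against 10.2% of tested genes (odds ratio 2.91, two-sided Fisher's exact test, adjusted p = 1.92e-05 over 8 tests) and on 3 of the 31 lower genes (9.68%). Marked genes had a median of 0 FPKM in control, against 2.88 FPKM for unmarked ones, and 51.6% of them were listed at 0 there, against 37.4% of all entries. Among genes tested from a control at 0, the mark was on 26 of 106 higher calls (24.5%) and on 21.6% of those tested, a difference that did not pass (two-sided Fisher's exact test, adjusted p = 0.467 over 16 tests). The authors' other mark, headed expression, was rarer among higher calls, on 8 of 122 (6.56%) against 21.8% of tested genes. Its odds ratio was 0.249 (two-sided Fisher's exact test, adjusted p = 1.92e-05 over the same 8 tests). It was on 2 of the 31 lower genes (adjusted p = 0.0623, same Fisher's exact test). This mark was not tested apart by control level.

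The next question was what remained 30 days after the drug was withdrawn. In the authors' deposited table, 100 RefSeq genes were higher and 50 were lower in recovery than in control at q under 0.05. IRS4, an insulin receptor substrate (X chromosome, 107975727 to 107979607), was listed at 0 in control, at 2.13 FPKM in treated cells and at 28.0 FPKM in recovery. DPM3 (36.2 FPKM), S100A6 (21.2 FPKM) and BEX1 (13.7 FPKM) were again higher than a control listed at 0. PRAME, a melanoma and testis antigen, rose from 19.2 FPKM in control to 78.8 FPKM in recovery (4.09-fold), FHL1, a LIM domain gene, from 148 to 560 FPKM (3.77-fold) and ZNF711 from 30.3 to 110 FPKM (3.62-fold). The other call above a control measured above 0 was NM_001282529, an identifier without a match in the name table, at 11.7 FPKM in control, 13.9 FPKM in treated cells and 617 FPKM in recovery. ABCC6P2 (27.5 FPKM in control), SMIM1 (11.8), EPCAM-DT, LINC01508 (10.9) and DHDH (9.47) were listed at 0 in recovery. Of the 50 lower genes, 3 were above 0 in recovery, the axon guidance gene SLIT2 (34.9 to 8.57 FPKM), SGMS2 (30.6 to 8.63 FPKM) and FAT3 (7.11 to 2.09 FPKM). FHL1, ZNF711, SLIT2, SGMS2 and FAT3 lie outside the naming rule and were chosen after their values were seen.

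No member of the stress or heat shock lists was called in recovery. The stress and amino acid genes had 0 of 23 calls in recovery, with DDIT4 at 142 FPKM, ASNS at 104 FPKM, TRIB3 at 45.9 FPKM and PHGDH at 138 FPKM. Heat shock genes had 0 of 13 calls, and HSPA8 stood at 213 FPKM, HSPA1B at 21.5 FPKM and DNAJA1 at 80.2 FPKM. Among 73 germline genes, 27 of them with q under 1, 3 were called higher, MAGEA3 (0 to 5.96 FPKM), PRAME and TDRD1 (0 to 2.50 FPKM). A one-sided Fisher's exact test gave adjusted p = 0.04 over 46 tests. The median log2 change of the 49 members with a mean of 0.5 FPKM or more was 1.52, at percentile 100. Here too, members at 0 in control entered the median only through their treated or recovery values. From a control at 0, the list held 2 of 96 higher calls and 8 of 258 tested genes (two-sided Fisher's exact test, adjusted p = 0.762 over 16 tests). With a control above 0, it held 1 of 4 higher calls and 19 of 10916 tested genes (adjusted p = 0.0201, same Fisher's exact test). DAZL was at 0.783 FPKM and SPANXC was listed at 0 again. Epithelial markers had 2 calls among 19, the transcription factor gene ELF3 (0 to 2.13 FPKM) and MUC1 (0 to 1.86 FPKM), with adjusted p = 0.0358 in the one-sided Fisher's exact test over 5 tested members. Neither list passed when only genes with a mean of 1 FPKM or more were tested.

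Single calls came from the interferon list, IFI16, a DNA sensor (0 to 4.48 FPKM), the kidney and adrenal list, NR5A1 (0 to 4.02 FPKM), and the blood list, CD68 (0 to 3.43 FPKM). The interferon list's median log2 change was 0.42 (percentile 99.8), with ISG15 at 34.2 FPKM and IFIT3 at 7.45 FPKM against 0.0791 FPKM in control, both without a call. Proliferation genes had 0 of 40 calls and a median log2 change of -0.29, at percentile 0.16; CENPE was at 29.2 FPKM in control and 13.7 FPKM in recovery and TTK at 57.2 and 28.1 FPKM. The histone list had 0 of 50 calls and a median log2 change of 0.46, at percentile 100. Imprinted genes (34 measured), methylation genes (22), p53 genes (30), protocadherins (18), nucleoside genes (23), apoptosis genes (27), metallothioneins (13), tumour suppressors (36), cholesterol genes (21), neuronal (28), fibroblast (15) and endothelial (14) markers, ribosomal protein (70) and housekeeping (25) genes and long noncoding RNAs (32) had 0 calls in recovery. Only 5 of the protocadherins, 6 of the metallothioneins and 11 of the neuronal markers had q under 1. DNMT1 was at 51.4 FPKM, DNMT3A at 10.3 FPKM, DNMT3B at 13.7 FPKM and UHRF1 at 25.4 FPKM. X-linked genes were 14 of the 100 higher genes (two-sided Fisher's exact test, adjusted p = 7.91e-05) and 0 of the 50 lower genes. The methylation mark was on 17 of the 100 higher genes (17.0%, two-sided Fisher's exact test, adjusted p = 0.0463) and on 9 of the 50 lower genes (18.0%, adjusted p = 0.106), against 10.1% of tested genes. Among genes tested from a control at 0, it was on 17 of 96 higher calls (17.7%) and 19.4% of those tested (two-sided Fisher's exact test, adjusted p = 0.719). X-linked genes were 12 of the 96 against 8.14% (adjusted p = 0.0962 in the same Fisher's exact test), and 11 of 94 against 5.60% without the germline list (adjusted p = 0.0146, same Fisher's exact test). From a control above 0 they were 2 of 4 against 3.64%, and 2 of 3 without the list (adjusted p = 0.0201 and 0.0147, same Fisher's exact test). Of the calls in recovery, 96 of 100 higher genes were listed at 0 in control and 47 of 50 lower genes were listed at 0 in recovery, which rests on 1 library.

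**Figure D2:**
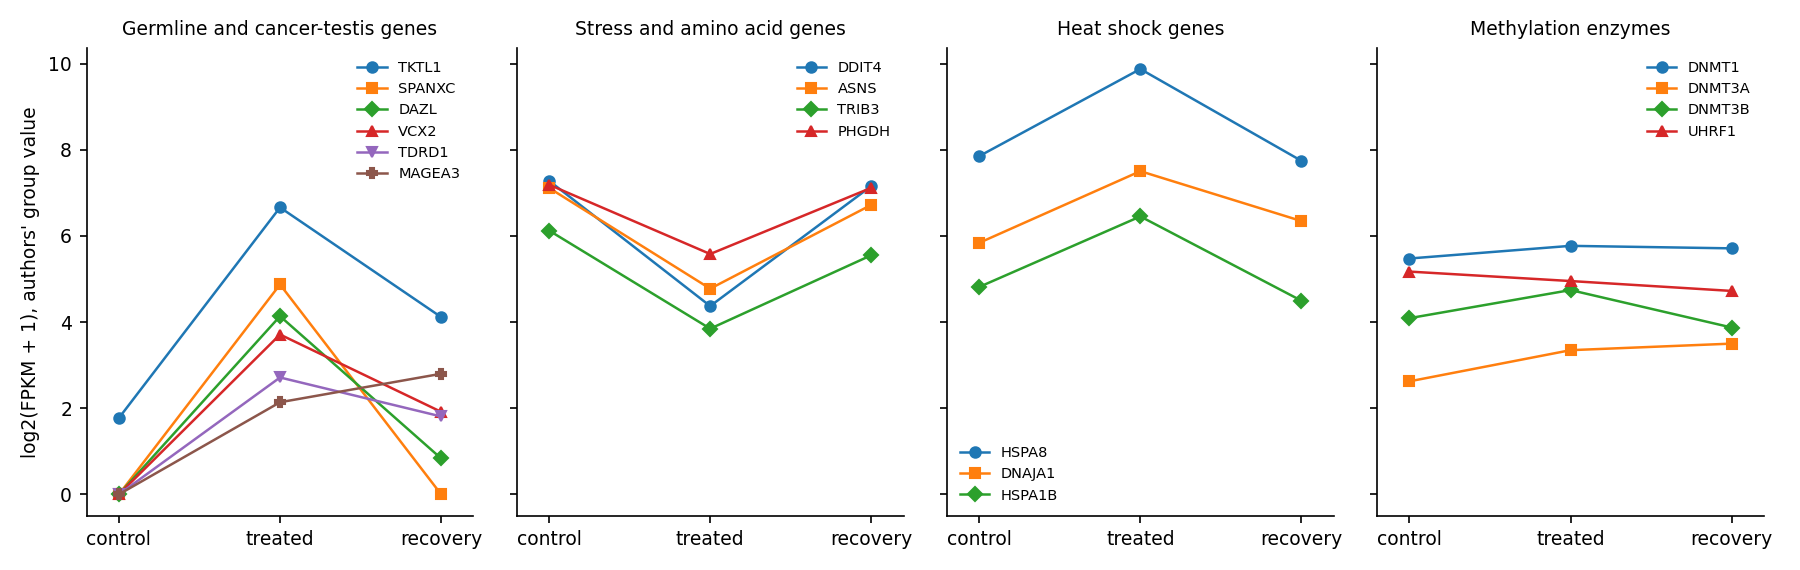
Group values as log2(FPKM + 1) in control, treated and recovery cells for germline, stress and amino acid, heat shock and methylation genes, 1 line per gene and 1 value per group, without error bars because each value is pooled over the libraries of its group. DDIT4 drops from 154 to 19.7 FPKM and returns to 142 FPKM, while TKTL1 is still at 16.3 FPKM in recovery; HSPA8 and the 4 methylation genes have no call.

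The calls of the 2 comparisons were then set side by side. Of the genes in the authors' deposited table, 41 were higher in both treated and recovery cells, among them DPM3, S100A6, BEX1, IRS4, MAP1LC3A, NR5A1, MAGEA3, TDRD1, ZNF711, RAI2 and CT55. Lower in both were 9, among them ABCC6P2, ECSCR and NR_033908. The number that went opposite ways was 0, but a gene at 0 in control cannot be lower in either comparison. Most higher calls started from such a control, so their part of this number was fixed in advance. Among the 10816 genes with q under 1 in both comparisons, 66 and 57 were called higher and 31 and 50 lower, and all 41 and 9 shared calls were among them. Independent lists of these sizes would share 0.348 and 0.143 genes, and unchanged groups set against the same control shared 4.34 and 2.12 genes in 100 simulations. The control libraries could not be split, so part of the excess may come from the shared control. Of the higher calls, 106 of 122 and 96 of 100 started from a control at 0, where only 296 and 258 genes had q under 1. Both higher lists draw on this small set, which neither expected number models, so the size of their excess is not known. For the 122 genes higher in treated cells, the median share of the log2 change still present in recovery was 0.576 (bootstrap 95% interval over genes 0.490 to 0.639), and 13 of them were listed at 0 in recovery. For the 31 lower genes it was 0.566 (0.368 to 0.742). Unchanged groups set against the same control gave 0.509 (95% of 100 simulations 0.425 to 0.604) and 0.502 (0.366 to 0.659), so neither RefSeq share lay outside that range. The simulation has no floor at 0, unlike the tables. Where control and treated values were both above 0, the shares were 0.347 and 0.168. Across 12712 genes the log2 changes of treated and recovery cells had r = 0.668, against 0.409 for simulated unchanged groups with a shared control. Genes are not independent replicates. Their covariance was 0.587, and the shared control would add 0.195 if its libraries varied like the others, which the tables do not show.

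**Figure D3:**
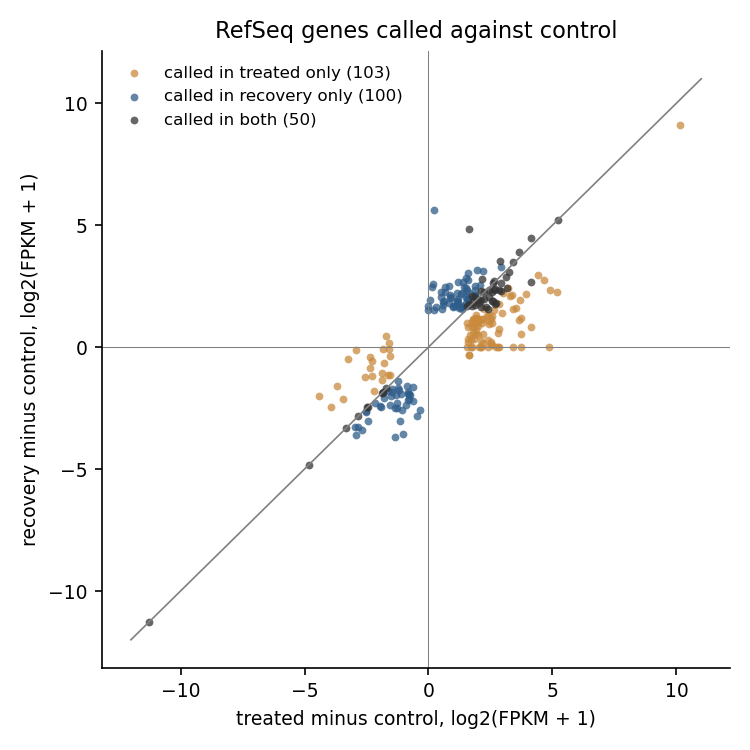
Log2(FPKM + 1) change from control in treated cells (x axis) and in recovery (y axis) for RefSeq genes called in treated cells (ochre), in recovery (blue) or in both (dark grey); each point is 1 gene and the diagonal marks equal changes. Of the genes called in both, 41 lie in the upper right and 9 in the lower left; IRS4, at 2.13 FPKM in treated cells and 28.0 FPKM in recovery, lies above the diagonal.

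No test of recovery against treated cells was deposited, so that comparison is given as values. MT1E went from 34.9 to 3.72 FPKM, TKTL1 from 100 to 16.3 FPKM, PHLDA2 from 14.2 to 3.55 FPKM, HSPA8 from 936 to 213 FPKM and POLR2A from 47.7 to 11.6 FPKM. IRS4 went from 2.13 to 28.0 FPKM and PRAME from 59.3 to 78.8 FPKM. H19 went from 490 to 33.0 FPKM.

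The lncRNA table was scaled apart from the RefSeq table, and its values are compared only within it. Its 21625 intact transcripts form 10010 loci of repeated values. In the authors' deposited table, 77 loci were higher and 52 lower in treated than in control cells at q under 0.05, and 86 were higher and 75 lower in recovery. TCONS_00028768 (chromosome 21, 35303426 to 35351160) was listed at 0 in control, at 661 FPKM in treated cells and at 1447 FPKM in recovery, and TCONS_00001406 (chromosome 1, 16123397 to 16126839) at 0, 1272 and 0 FPKM. TCONS_00017137 (X chromosome, 8196412 to 8423740) was at 5095 FPKM in control and listed at 0 in both other groups, and TCONS_00026389 (chromosome 18, 106602 to 108335) was at 2145, 0 and 234 FPKM. H19 was at 751, 4830 and 1372 FPKM in this table, a treated ratio of 6.43, with q = 0.061 in the authors' deposited table. Both comparisons shared 24 higher and 31 lower loci, and 0 went opposite ways. A locus at 0 in control cannot be lower in either comparison, which fixed that last number for most higher loci. Among the 813 loci with q under 1 in both, 36 and 42 were called higher and 52 and 75 lower. Independent lists of these sizes would share 1.86 and 4.80 loci, and simulated unchanged groups with a shared control 7.37 and 14.9. Of all higher calls, 74 of 77 and 82 of 86 had a control at 0, which these numbers do not model. The median share of the log2 change present in recovery was 0.762 for the 77 higher loci (bootstrap 95% interval 0.611 to 0.815). The central 95% of simulated unchanged groups without a floor at 0 was 0.363 to 0.651. That range cannot judge the share, because 74 of the 77 loci had a control at the floor, which the simulation does not model. For the 52 lower loci no such comparison can be made either, because 31 were listed at 0 in recovery. A locus at 0 in both groups has a share of 1 by construction. Of the 77 higher loci in treated cells 74 had a control listed at 0, and of the 52 lower loci 51 were listed at 0 when treated.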

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

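The alternatives at q under 0.10, with both values above 0, per transcript, with every gene as background and by list percentile were added after seeing the data; the others were fixed earlier. No paired analysis was possible because the tables hold 1 value per group. For that reason the fits without an eBayes trend, with only 2 groups, with a replicate block, without a control or treated replicate, with an estimated camera correlation and with split controls were not run, nor was any count for recovery against treated. Another pseudocount or scaling cannot change the authors' calls.

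With control and group both above 0, RefSeq calls were 16 higher and 9 lower in treated and 4 higher and 3 lower in recovery, and lncRNA calls 3 higher and 1 lower in treated and 4 higher and 0 lower in recovery; fewer genes qualify by construction. At q under 0.10, 49 RefSeq genes were lower and 122 lncRNA loci higher in treated cells, and 135 lncRNA loci were higher in recovery. Counted per transcript, which repeats a locus, lncRNA calls were 487 higher and 134 lower in treated and 445 higher and 230 lower in recovery. The lists passing in treated cells, 3 as reported, were 5 with every gene as background, 5 at q under 0.10 (without the imprinted list) and 10 by percentile. Heat shock genes, for rises, and histone genes, for falls, passed both with every gene as background and at q under 0.10. The lists passing in recovery, 2 as reported, were 0 with a mean of 1 FPKM or more, 0 with every gene as background, 0 at q under 0.10 and 6 by percentile. The retained share of higher genes was 0.727 with a pseudocount of 0.1 and 0.347 with control and treated both above 0, and that of lower genes 0.360 and 0.168. The correlation was 0.701 with a pseudocount of 0.1, 0.653 without a filter, 0.678 with a mean of 1 FPKM or more and 0.648 after quantile scaling. Where construction does not show it, the cause was not tested. The other 64 such values stayed within their limits.

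Of 361 log2 changes of named genes, 8 changed sign or became 0 in some setting, none of them called: in treated cells EMC7 (0.00567 after median-ratio and 0.0438 after quantile scaling), EPCAM (-0.28) and CENPE (0.0316), and in recovery PMVK (-0.0165), INA (-0.19), ESAM (-0.21), RPL32 (0) and TEK (-0.14), all after quantile scaling; the cause was not tested. The recovery values rest on 0.652 times the fragments of the control, which limits low genes there most.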

Other observations

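All tests in this part were chosen after the result was seen. Many genes lay far above a control measured above 0 without a call. At 5 FPKM or more in treated cells and at least 10-fold above control stood 116 RefSeq genes, of which 2 were called, TKTL1 and PEG10; their median control value was 0.509 FPKM. Of these, 17 were in the cancer-testis and germline list, among 24 members above 0 in control and with q under 1 (odds ratio 266, two-sided Fisher's exact test, adjusted p = 5.30e-28 over 21 tests). All 21 tests, including that of the histone genes below, used only genes that meet both conditions. They did not match genes on control level, and a gene low in control reaches a 10-fold rise more easily. Such a gene can also have q under 1 because its treated value is high. The odds ratios and p-values therefore cannot tell list membership from a low control value. Of the 17, 12 were also at least 10-fold above control in recovery. Whole numbers of fragments were found for 65 of the 116. The smallest in control, treated and recovery were 1, 177 and 6 for SSX1, 1, 160 and 22 for MAGEA11, 3, 250 and 59 for MAGEB2 and 3, 222 and 11 for MAGEA1. CTAG2, a cancer-testis antigen, was at 0.658, 51.1 and 44.6 FPKM. As said above for this list, how fragments were shared among related members is not given.

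Replication-dependent histone genes formed the other large group, with 11 of 49 members above 0 in control and with q under 1 (odds ratio 29.8, two-sided Fisher's exact test, adjusted p = 2.52e-11). Of the 11, 9 were also at least 10-fold above control in recovery. The smallest whole numbers of fragments were 3, 492 and 178 for the linker histone gene H1-1, 1, 223 and 37 for H2BC3 and 4, 195 and 56 for H1-5. These genes are near copies of one another, so fragments cannot be assigned to single members with certainty. The interferon-stimulated genes ISG15 (1, 86 and 56 fragments) and IFI27 were also in the set. That is 2 of the 33 list members above 0 in control and with q under 1 (adjusted p = 0.249 in the same two-sided Fisher's exact test).

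Of the 122 genes called higher in treated cells, 106 start from a control listed at 0. Of germline genes listed at 0 in control, 18 of 45 reached 2 FPKM in treated cells (12 of them called), against 5 of 58 markers of other tissues (3 called; two-sided Fisher's exact test, adjusted p = 0.000705 over 6 tests, highest 0.00146 at 1 FPKM), although 3 of 73 and 28 of 118 members had 2 FPKM in control. This argues against failed control estimates that strike both kinds of gene alike as the whole cause in treated cells, while failures tied to the kind of gene stay open, as do both in recovery (9 of 45 against 3 of 58, adjusted p = 0.0404; 13 of 45 against 8 of 58 at 1 FPKM, adjusted p = 0.0839, same Fisher's exact test). Treated values rest on 1.32 times the fragments of control, but fewer fragments are argued against as the whole cause of the control zeros: 1 fragment is worth 1.53 times as much FPKM in recovery as in control, yet 6547 genes were listed at 0 in recovery and 7562 in control. For the other 94 genes failed estimates stay open, because 275 RefSeq genes were listed at 0 in control alone with 1 FPKM or more in both other groups, against 27 for treated and 56 for recovery.

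Large differences from a control above 0 were rarely called. At 5 FPKM or more in treated cells, 43 of 95 genes with a control at 0 were called (45.3%), against 2 of 116 genes at least 10-fold above a positive control (1.72%; two-sided Fisher's exact test, adjusted p = 9.28e-16 over 4 tests). A dependence of the authors' test on an exact 0 may explain this. The median treated value was 14.4 FPKM for the genes with a positive control and 9.48 FPKM for those at 0. These medians cannot decide whether a lower final level plays a part, because the 10-fold rule raised the level of the genes with a positive control only. No biological explanation was tested.

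H19 had a treated ratio of 51.6 in the RefSeq table and 6.43 in the lncRNA table. Separate scaling of the tables would shift every gene alike, but after removing the tables' commonest ratio H19 still differed between them by 1.89 in control, -1.24 in treated and 0.96 in recovery on the log2 scale, a range of 3.12, which argues against scaling as the whole cause. Different transcript models in the 2 tables may account for the rest and were not tested.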
